A study of Harpegnathos saltator with 19 samples.

How the data were processed

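The series holds RNA-seq of the central brain of Harpegnathos saltator workers, an ant in which workers can become reproductives. Each library came from the brain of a single ant, taken 10 h after an injection into the head, per the labels. The ants received 100 ng of 20-hydroxyecdysone (20E, the active moulting hormone of insects), 100 ng of juvenile hormone III (JH3), or the DMSO control. The labels give 7 libraries for 20E, 7 for JH3 and 5 for DMSO, and the series text describes them as biological replicates. Poly(A) RNA from 600 ng of total RNA was made into strand-specific libraries by the dUTP method, per the labels' protocols. The sample descriptions carry 2 run labels: 190514 holds replicates 1 to 3 of each group, and 200212 holds replicates 4 to 7 of 20E and JH3 and replicates 4 and 5 of DMSO.

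The authors deposited 1 table of FPKM values (fragments scaled to gene length and library depth) for 14001 genes and 19 libraries, named by NCBI gene numbers. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2; their versions, the genome build and the annotation are not given in the sources used here. The deposited FPKM values of each library fell on a regular grid, from which whole read numbers could be read back for 14001 genes (100%, within 0.02 of a whole number). These give a depth of 14.05 to 26.09 M reads on genes per library, with a median of 18.31 M. The median tested gene had 577 reads in its median library, and 5.1% of the tested genes had fewer than 50 reads. The grid also showed that the authors' scaling did not follow total reads: its ratio to total reads ran from 0.763 to 1.12 among the libraries. A relative gene length was taken from the same grid.

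Gene symbols came from a RefSeq gene table of the assembly Hsal_v8.6, which matched 13989 of the 14001 identifiers and left 12 without a match. A symbol other than a LOC number was available for 4117 genes (29.4%). Because the authors' build is not known, no coordinates are given. Where a symbol is that of a fly gene, the function stated is that of the fly gene.

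Genes were tested where FPKM reached 1 in at least 5 libraries, which kept 9381 genes (67%). The values were taken as log2(FPKM + 0.5) and fitted with limma 3.58.1 in R 4.3.3, using 1 mean per group, the run label as a term and a trended prior variance over all 19 libraries. The 3 comparisons were 20E with DMSO, JH3 with DMSO, and 20E with JH3. P-values are two-sided and Benjamini-Hochberg adjusted within each comparison, with a threshold of 0.05. Because 0.5 is added before the logarithm, folds of genes near or below 1 FPKM are smaller than the ratio of their means. The same model was refitted within each run label, and a term for a different hormone effect in each run was tested. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

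The groups, the test, its filters, the alternatives, the rule for named genes and 24 gene lists were fixed before the data were examined. The lists cover ecdysone response and receptors, juvenile hormone response and metabolism, ecdysteroid synthesis, neuropeptides and peptide hormones (with their receptors and processing enzymes), neurotransmitter receptors, activity-regulated early genes, immune response, heat shock and chaperones, circadian clock, insulin and TOR signalling, detoxification enzymes, lipid synthesis and transport, cuticle and pigmentation, ribosomal proteins, oxidative phosphorylation and proteasome. They also hold markers of neurons, glia, photoreceptors and eye, fat body and haemolymph, muscle, haemocytes, head glands, and olfactory and gustatory organs. The lists were fixed as product names, which the tables do not give, so they were translated into symbols before any test was run. The translation also added members that the fixed product names do not cover. Among them were Gat-a, Gli and Nrx-IV (glia), rdgA and sev (eye), ILP-2 and rictor (insulin and TOR), Mtp and Lsd-1 (lipid), Cyp18a1 (detoxification) and drpr (haemocytes). Such members were not part of the lists fixed beforehand, and several list calls given below rest on them. Vitellogenin and the juvenile hormone receptor partners Met and tai had no symbol of that name and are not analysed here. Lists with at least 3 measured members (22 of 24) were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma, adjusted over the lists within a comparison.

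For each comparison the text names the 10 largest rises and the 10 largest falls among genes past the threshold that have a symbol and the same sign in both runs. It also names members of the ecdysone and juvenile hormone lists, up to 4 members of each other list, the hormone receptors, Kr-h1 and corazonin. Any other gene named was chosen after its values were seen. Each reported value of a gene is relative to the spread between libraries, as mean ± SD of FPKM or log2 fold change ± SE.

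The model was tested on simulated data made from the real genes, with 200 genes changed by known folds. For 20E against DMSO (9359 genes tested) it recovered 66% of the genes changed 1.5-fold, 88% at 2-fold and 98% at 4-fold. For JH3 against DMSO (9356 genes) these shares were 68%, 84% and 100%, and for 20E against JH3 (9361 genes) 66%, 92% and 100%. Among the calls, 4.9%, 5.4% and 6.8% were false. The simulated genes were drawn independently, without deviations that run through a whole library, so these shares may not hold for the real libraries. Pairs of libraries of a group were compared by a chi-square of their reads over genes; the 52 pairs gave 19.1 to 245 per degree of freedom, so no library was a copy of another of its group. Pairs across groups were not compared.

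Both hormone groups were set against the same DMSO libraries, so their correlation was compared with 100 simulations of unchanged groups and with 20 splits of the DMSO libraries into sets of 2 and 3. Alternatives were other pseudocounts (0.1 and 1), filters (no filter, 0.1 and 5 FPKM), scalings (median ratio, quantile), no run term, the replicate number as a block, each run alone, only the libraries of the groups compared, library weights, robust variances, and each library left out in turn. Chosen after seeing the data were voom on the reads read back, scaling to total reads, removal of a trend with relative gene length from every library, and leaving out 20E replicate 6 and JH3 replicate 1 together, the libraries with the lowest array weights (0.14 and 0.21).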

Results

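RNA-seq libraries were made from the central brains of 19 Harpegnathos saltator workers, each taken 10 h after an injection of 20E (7 ants), JH3 (7 ants) or the DMSO control (5 ants). In insects 20E drives moulting through the nuclear receptor pair EcR and Ultraspiracle, and JH3 is a form of juvenile hormone, which acts through the zinc finger factor Krüppel homolog 1 (Kr-h1). The reads on genes numbered 21.72 ± 3.21 M in DMSO (SD, n = 5, 18.27 to 25.51), 18.35 ± 2.65 M in 20E (n = 7, 15.58 to 22.71) and 18.93 ± 4.46 M in JH3 (n = 7, 14.05 to 26.09). Levels are the authors' FPKM values. Of the 9381 genes tested, 4779 (50.9%) differed between the run labels by limma, so the run was a term of every fit. No gene had a hormone effect that differed between the runs after adjustment by limma (0 genes in each comparison, with 207, 450 and 248 genes at an unadjusted p under 0.05 for 20E with DMSO, JH3 with DMSO and 20E with JH3). Each group held 2 to 4 libraries per run, so a hormone effect that differed between the runs could go undetected. Adjusted p-values are limma's with Benjamini-Hochberg adjustment.

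The comparison of 20E with DMSO asks which brain transcripts responded to the moulting hormone. Genes of the ecdysone cascade were among the largest rises. Hr4 (LOC105190338), a nuclear receptor of that cascade, went from 1.15 ± 0.35 FPKM (SD, n = 5) in DMSO to 33.1 ± 8.22 FPKM (n = 7) in 20E. This is a log2 fold change of 4.28 ± 0.14 (SE, adjusted p = 4.39e-13, within the runs 4.35 and 4.18). E75 (LOC105187469), an early response gene encoding another nuclear receptor, went from 74.4 ± 11.5 to 619 ± 137 FPKM (log2 2.96 ± 0.13, adjusted p = 5.55e-11, 2.94 and 3.01 within the runs). Genes outside the ecdysone list rose too. The cadherin gene Cad74A (LOC105191639) went from 10.3 ± 1.71 to 94.7 ± 28.1 FPKM (log2 3.13 ± 0.22, adjusted p = 2.56e-08, 3.33 and 2.87 within the runs). Falls were smaller. Gycalpha99B (LOC105180850), which encodes a subunit of soluble guanylate cyclase, went from 72.3 ± 8.88 to 35.2 ± 6.09 FPKM (log2 -1.0 ± 0.12, adjusted p = 4.41e-05).

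In all, 313 of 9381 genes passed the threshold, 243 higher and 70 lower in 20E. At an unadjusted p under 0.05 there were 848 genes. More than 2-fold changes were 59 of the rises and 4 of the falls. A symbol was available for 133 of the 313 genes, and the 313 genes had the same sign in both runs. In 49 of the 52 named genes with a call, all 7 20E libraries lay beyond the DMSO mean. Both checks use the libraries that gave the calls, here and in the other comparisons, so neither is independent support. With scaling to total reads in place of the authors' scaling the split was 228 higher and 110 lower (67.5% higher against 77.6%). The count was 551 with library weights, 193 without the run term, and 120 and 50 within the runs. The lower genes numbered 112 without 20E replicate 6, 43 without DMSO replicate 5, and 46 without DMSO replicate 2 or 20E replicate 3.

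**Figure D1:**
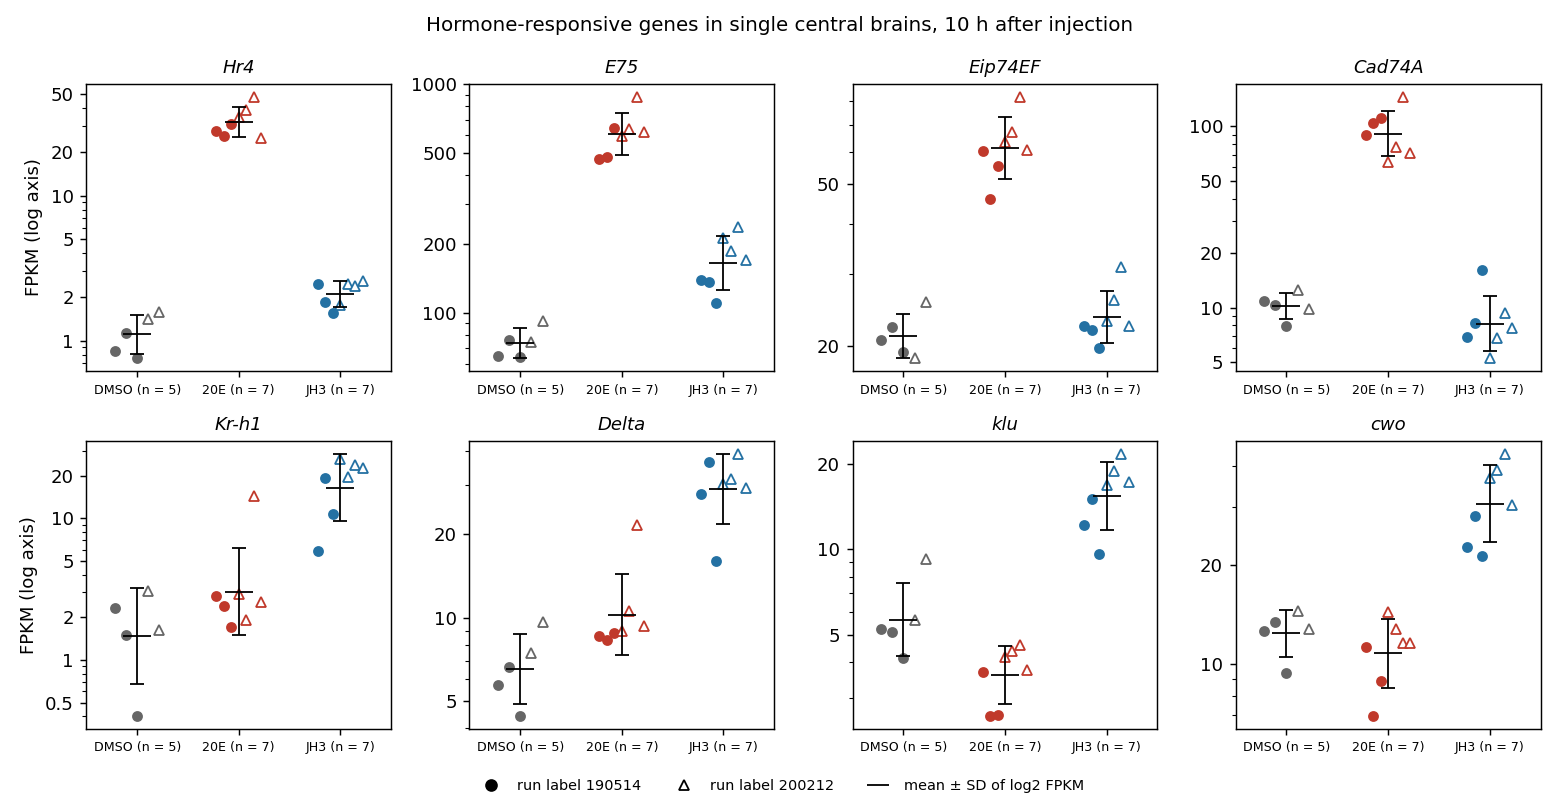
FPKM (log axis) of 8 genes in each library of the DMSO (5), 20E (7) and JH3 (7) groups, with filled circles for run label 190514, open triangles for 200212, and bars for the mean ± SD of log2 FPKM. Hr4, E75, Eip74EF and Cad74A stood highest in 20E, and Kr-h1, Delta, klu and cwo highest in JH3, with 20E replicate 6 at 14.4 FPKM for Kr-h1 and 21.6 for Delta.

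Of the 18 measured members of the ecdysone list, 8 rose under 20E, none fell and 10 did not pass. The count was 10 when adjusted over the list alone. Besides Hr4 and E75, E23, an ABC transporter gene, rose by log2 1.80 ± 0.31 (2.65 and 0.87 within the runs). With it rose the ETS factor gene Eip74EF (1.47 ± 0.11), Cyp18a1, whose enzyme inactivates ecdysteroids (1.42 ± 0.28), and the nuclear receptor genes Hr3 (0.71 ± 0.12) and Hr39 (0.71 ± 0.13). Eip63E rose by 0.39 ± 0.07, and the adjusted p of these genes ran from 4.24e-08 to 0.00453. The receptor genes themselves did not pass. Ecr had 6.13 ± 0.649 FPKM in DMSO and 6.54 ± 1.21 in 20E (log2 0.05 ± 0.11, adjusted p = 0.999). For usp the levels were 34 ± 5.17 and 47.6 ± 12.1 FPKM (log2 0.46 ± 0.17, adjusted p = 0.261). Nor did br (log2 0.06 ± 0.22, adjusted p = 0.999) or Hr38 (-0.17 ± 0.23, adjusted p = 0.999). The list passed camera (adjusted p = 2.81e-16, and adjusted p = 0.0352 with an estimated correlation) and fry (adjusted p = 4.33e-06). Without 20E replicate 6 and JH3 replicate 1 it was adjusted p = 0.238 with an estimated correlation. Kr-h1, the juvenile hormone response gene, had a log2 fold change of 0.66 ± 0.39 (adjusted p = 0.774). None of the 3 measured members of the juvenile hormone list passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.864).

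The other large rises were sing (log2 2.92 ± 0.19), known from myoblast fusion, and stan (2.42 ± 0.19), a cadherin of planar polarity. Np (2.04 ± 0.18), a tracheal serine protease gene, rose too, as did Gasp (1.88 ± 0.39), which encodes a chitin-binding protein of tracheae. With them rose oys (1.84 ± 0.23), a phospholipid acyltransferase gene, and pyd (1.75 ± 0.15), which encodes a junction protein. The adjusted p of these genes ran from 1.69e-08 to 0.00706. Gasp and sing lay below 1 FPKM in DMSO (0.536 ± 0.556 and 0.218 ± 0.068 FPKM, n = 5). Voom on the reads read back gave log2 2.90 and 4.45 for them. Of the genes without a symbol, LOC112588181 (0.867 ± 0.153 to 17 ± 8.96 FPKM, log2 3.56 ± 0.24) and LOC105185734 (0.997 ± 0.401 to 11.1 ± 5.64 FPKM, log2 3.0 ± 0.19) rose the most. They are named because of these values.

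Among the falls were Cyp4aa1, a cytochrome P450 gene (log2 -1.06 ± 0.17, and -1.67 by voom), and the Toll-family receptor gene Toll-6 (-0.81 ± 0.10). Others were the RNA polymerase subunit gene Rpb8 (-0.77 ± 0.14) and the ETS factor gene Ets97D (-0.77 ± 0.08). The transcription factor genes ken (-0.76 ± 0.12) and klu (-0.67 ± 0.13) and the sodium channel subunit gene Teh4 (-0.60 ± 0.13) also fell. The adjusted p of these falls ran from 3.38e-06 to 0.0139. The clock gene per (-0.77 ± 0.19, adjusted p = 0.0315, lower in 6 of 7 20E libraries than the DMSO mean) and sev, a receptor tyrosine kinase gene of the eye (-0.60 ± 0.15, adjusted p = 0.0312, lower in 6 of 7), passed more narrowly. The call of per ended when any of DMSO replicates 1, 2, 4 and 5 or 20E replicates 2 to 4 was left out (-0.80 to -0.67). That of sev ended without any of DMSO replicates 2, 4 and 5 or 20E replicates 1 to 4 and 7 (-0.60 to -0.54), and that of Teh4 without DMSO replicate 5 (-0.54).

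In the circadian list (8 measured) cyc, the partner of Clk, rose (log2 1.04 ± 0.17, adjusted p = 0.000758) and per fell. There were 2 higher and 1 lower when adjusted over the list alone, and the list had a camera adjusted p of 0.864. The serotonin receptor gene 5-HT2A rose from 5.97 ± 0.768 to 14.3 ± 3.7 FPKM (log2 1.17 ± 0.15, adjusted p = 8.79e-05). It was the only one of 35 neurotransmitter receptor genes to pass, also when adjusted over the list alone (camera adjusted p = 0.35). Of 26 genes of neuropeptides, their receptors and their processing 2 rose, also when adjusted over the list alone (camera adjusted p = 0.355). They were ILP-2, an insulin-like peptide gene (0.55 ± 0.13, adjusted p = 0.0231), and SIFR, the gene of the SIFamide receptor (1.31 ± 0.31, adjusted p = 0.0201). ILP-2 was also the only call among 18 insulin and TOR genes, adjusted over the list alone too (camera adjusted p = 0.421). The calls of ILP-2 (0.50 to 0.53) ended without DMSO replicate 4, DMSO replicate 5 or 20E replicate 3. Those of SIFR (1.06 to 1.26) ended without DMSO replicate 1, DMSO replicate 3 or 20E replicate 3. Corazonin, a neuropeptide gene known for differing between castes of this ant, had 27.4 ± 8.84 FPKM in DMSO and 23.4 ± 9.15 in 20E (Crz, log2 -0.17 ± 0.21, adjusted p = 0.999).

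Among the cell type markers, rdgA, a diacylglycerol kinase gene of photoreceptors, rose (log2 1.06 ± 0.12, adjusted p = 2.41e-05) and sev fell of 16 eye genes. The counts were 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.864). Of 9 glial markers Gli, a septate junction gene, rose (0.57 ± 0.14, adjusted p = 0.0237). In this list 2 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.766). The Gli call ended without any of DMSO replicates 1, 3, 4 and 5 or 20E replicates 1 and 3 (0.53 to 0.58). None of the 16 neuron markers passed, over all genes or adjusted over the list alone. Yet the list had a camera adjusted p of 0.0342 with a median log2 fold change of 0.14, which became adjusted p = 0.982 with an estimated correlation. The mean log2 level of the list was 6.42 in 20E replicate 6, against 5.68 to 6.07 in the other 20E libraries. In the detoxification list (14 measured) Cyp18a1 rose and Cyp4aa1 fell, and in the cuticle list (19 measured) Gasp rose. The counts were the same when adjusted over the list alone (camera adjusted p = 0.355 and 0.864). No member passed among 6 activity-regulated early genes, 15 immune genes, 18 heat shock genes, 18 lipid genes, 8 fat body, 16 muscle, 4 haemocyte and 8 chemosensory markers. The same held for 58 ribosomal protein genes, 53 oxidative phosphorylation genes and 32 proteasome genes. The camera adjusted p of these lists ran from 0.195 to 0.955. Adjusted over the list alone, 1 haemocyte marker was higher and 1 chemosensory marker lower, and no other member of these lists passed. The ecdysteroid synthesis list (2 measured, median log2 0.06) and the head gland list (1 measured, -0.15) were too short for a list test. They had no call, over all genes or when adjusted over the list alone.

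**Figure D2:**
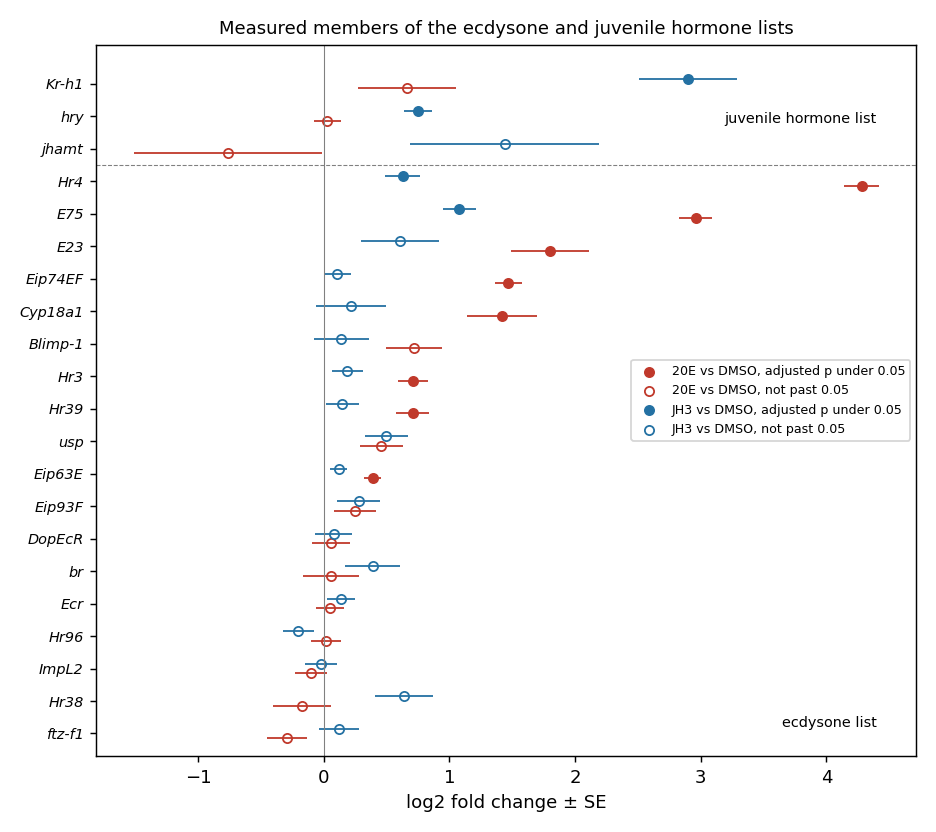
Log2 fold changes ± SE of the 18 measured members of the ecdysone list and the 3 of the juvenile hormone list, for 20E with DMSO (red, 7 against 5 libraries) and JH3 with DMSO (blue, 7 against 5); filled points have an adjusted p under 0.05. Under 20E 8 ecdysone members passed, up to 4.28 for Hr4, and under JH3 Kr-h1 (2.90) and hry (0.75) passed with E75 (1.08) and Hr4 (0.63).

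The comparison of JH3 with DMSO asks the same of juvenile hormone. Kr-h1 (LOC112589664), the transcription factor gene that juvenile hormone induces in insects, rose from 1.79 ± 1.01 FPKM (SD, n = 5) to 18.3 ± 7.36 FPKM (n = 7). This is a log2 fold change of 2.90 ± 0.39 (adjusted p = 0.000314, within the runs 2.70 and 3.08). Delta (LOC105191219), which encodes a ligand of the Notch receptor, rose from 6.79 ± 1.95 to 30 ± 7.29 FPKM (log2 1.99 ± 0.20, adjusted p = 1.47e-05, 2.09 and 1.86 within the runs). With it rose Sidpn (1.68 ± 0.15), cwo (1.19 ± 0.13) and hry (0.75 ± 0.11), which encode related bHLH repressors, cwo in the clock. E75 was 2.11-fold higher (170 ± 45.2 FPKM, log2 1.08 ± 0.13, adjusted p = 0.000132), against 7.76-fold under 20E. The largest rises were in genes without a symbol, LOC105186969 (3.49 ± 1.19 to 91.9 ± 24.9 FPKM, log2 4.55 ± 0.21) and LOC105192299 (0.279 ± 0.1 to 11.5 ± 3.46 FPKM, log2 3.91 ± 0.16). They are named because of these values.

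In all, 87 of 9381 genes passed, 59 higher and 28 lower in JH3, with 778 at an unadjusted p under 0.05. More than 2-fold changes were 16 rises and 1 fall. The fall was LOC105187714 (3.36 ± 0.376 to 0.873 ± 0.42 FPKM, log2 -1.51 ± 0.25). A symbol was available for 41 of the 87 genes, and the 87 genes had the same sign in both runs. In 32 of the 33 named genes with a call, all 7 JH3 libraries lay beyond the DMSO mean. The count was 134 without 20E replicate 6 and JH3 replicate 1, 151 with scaling to total reads and 159 with the gene length trend removed. It was 180 with library weights, 49 without the run term, and 14 and 8 within the runs. The lower genes numbered 15, 16 and 17 without DMSO replicates 4, 2 and 5 in turn.

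Other named rises were Oatp74D (log2 1.68 ± 0.22), whose transporter carries ecdysone into cells, and the zinc finger gene klu (1.27 ± 0.13). With them rose Pdk1 (1.26 ± 0.17), Glut4EF (1.26 ± 0.17) and the ETS factor gene Ets98B (1.21 ± 0.12), with adjusted p from 1.47e-05 to 0.00038. The falls were smaller, among them rau (-0.86 ± 0.13), Toll-6 (-0.75 ± 0.10), Gycalpha99B (-0.71 ± 0.12) and nab (-0.44 ± 0.08), with adjusted p from 0.000184 to 0.00802. The peroxisomal transporter gene ABCD (-0.68 ± 0.15), spri (-0.66 ± 0.15), the receptor kinase gene Gprk1 (-0.44 ± 0.10) and the chondroitin synthase gene Chsy (-0.43 ± 0.08) passed at adjusted p between 0.0108 and 0.0462. The calls of ABCD (-0.69 to -0.57) ended without any of DMSO replicates 2 to 5 or JH3 replicates 1 and 5. That of Chsy (-0.41 to -0.40) ended without DMSO replicate 4 or 5. Those of spri (-0.70 to -0.55) ended without any of DMSO replicates 2 to 5 or JH3 replicates 1 and 4 to 7. Gprk1 (-0.49 to -0.37) kept its call only without JH3 replicate 1.

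In the juvenile hormone list (3 measured) Kr-h1 and hry rose, also when adjusted over the list alone. The list passed camera (adjusted p = 2.22e-06, adjusted p = 0.0148 with an estimated correlation) and fry (adjusted p = 0.000114). With the replicate number as a block it was adjusted p = 0.0612 with an estimated correlation. The other measured member, jhamt, which encodes an enzyme of juvenile hormone synthesis, did not pass (log2 1.44 ± 0.75, adjusted p = 0.642). In the ecdysone list E75 and Hr4 rose of 18, and 4 rose when adjusted over the list alone. Camera gave an adjusted p of 1.3e-05, which was adjusted p = 0.375 with an estimated correlation. Hr4 went from 1.15 ± 0.35 to 2.14 ± 0.416 FPKM (log2 0.63 ± 0.14, adjusted p = 0.0322). The call ended without any of DMSO replicates 1, 3 and 4 or JH3 replicates 1, 2 and 5 to 7 (0.56 to 0.65). Not past the threshold were Eip74EF (log2 0.11 ± 0.11, adjusted p = 0.709), Hr3 (0.19 ± 0.12, 0.663) and Ecr (0.14 ± 0.11, 0.687). Nor did usp (0.50 ± 0.17, 0.318), br (0.39 ± 0.22, 0.648) or Hr38 (0.64 ± 0.23, 0.342) pass. Corazonin had 26.3 ± 6.12 FPKM in JH3 (Crz, log2 0.05 ± 0.21, adjusted p = 0.935).

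Of 9 glial markers 2 fell under JH3, and 5 fell when adjusted over the list alone (camera adjusted p = 9.26e-06, adjusted p = 0.313 with an estimated correlation, fry adjusted p = 0.0939). The falls were in moody, a receptor gene of the glial blood-brain barrier (35.8 ± 7.25 to 21.6 ± 5.96 FPKM, log2 -0.63 ± 0.13, adjusted p = 0.0222), and in Gat-a, a GABA transporter gene (54.1 ± 7.23 to 34.5 ± 7.89 FPKM, log2 -0.62 ± 0.14, adjusted p = 0.0398). The call of moody ended without any of DMSO replicates 2 to 5 (-0.62 to -0.58). That of Gat-a ended without any of DMSO replicates 2, 4 and 5 or JH3 replicates 1 and 4 to 7 (-0.64 to -0.50). Among 18 insulin and TOR genes foxo, the transcription factor that insulin signalling restrains, rose from 4.76 ± 1.51 to 9.18 ± 1.67 FPKM (log2 0.84 ± 0.13, adjusted p = 0.00135). Adjusted over the list alone 1 was higher and 2 lower (camera adjusted p = 0.359). In the circadian list cwo was the only call of 8, also when adjusted over the list alone (camera adjusted p = 0.336). Ribosomal protein genes (58 measured, median log2 0.12) and oxidative phosphorylation genes (53 measured, median 0.08) had camera adjusted p of 9.26e-06 and 0.0031. They had no member past the threshold, over all genes or adjusted over the list alone. With an estimated correlation these were adjusted p = 0.674 and adjusted p = 0.683. Over all 9381 genes the log2 fold changes correlated with relative gene length at Spearman -0.21, a trend that can also shift whole lists. The remaining lists had no call, over all genes or adjusted over the list alone. Those long enough for camera gave adjusted p from 0.0603 to 0.737.

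The direct comparison of 20E with JH3 asks where the hormones differ, and does not use the DMSO libraries as a reference. Of 18 ecdysone genes 8 were higher in 20E, led by Hr4 (log2 3.65 ± 0.13, adjusted p = 1.26e-12, within the runs 3.57 and 3.71). The cadherin gene Cad74A was higher by 3.41 ± 0.20 (adjusted p = 2.49e-09, 3.31 and 3.48 within the runs). Kr-h1 (-2.24 ± 0.35, adjusted p = 0.000349, -2.01 and -2.40 within the runs) and klu (-1.95 ± 0.11, adjusted p = 2.49e-09, -1.87 and -2.01 within the runs) were the lowest in 20E among genes past the threshold with a symbol. Clock genes moved in opposite directions: cyc (1.29 ± 0.15) and Clk (0.54 ± 0.13) were higher in 20E, and cwo (-1.46 ± 0.12) and per (-0.87 ± 0.18) lower. Of 18 insulin and TOR genes 2 were higher in 20E and 1 lower. ILP-2 stood at 15.3 ± 3.45 FPKM in 20E and 7.38 ± 1.25 in JH3 (log2 0.99 ± 0.12, adjusted p = 1.74e-05). For foxo the levels were 4.56 ± 0.959 and 9.18 ± 1.67 FPKM (log2 -0.94 ± 0.12, adjusted p = 2.35e-05).

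Here 501 of 9381 genes passed, 366 higher and 135 lower in 20E, with 1300 at an unadjusted p under 0.05. Differences of more than 2-fold were 72 of the higher and 22 of the lower genes. A symbol was available for 213 of the 501 genes, and the 501 genes had the same sign in both runs. In 52 of the 58 named genes with a call, all 7 20E libraries lay beyond the JH3 mean. For 363 of the 501 (72.5%) the estimates against DMSO had opposite signs, and 234 were called in neither comparison with DMSO. Among all 9381 genes 61.7% had the same sign. The direct comparison tests the difference of these 2 estimates, so its calls favour opposite signs by selection. The count was 788 with library weights (525 higher and 263 lower), 313 without the run term, and 169 and 160 within the runs. With total reads the split was 324 higher and 184 lower (63.8% higher against 73.1%), and with the length trend removed 405 and 198.

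The named higher genes were sing (log2 2.52 ± 0.18), Np (2.31 ± 0.16), stan (2.06 ± 0.17), and pyd (1.88 ± 0.14). Further ones were E75 (1.88 ± 0.12), oys (1.81 ± 0.20), Gasp (1.73 ± 0.35) and spri (1.60 ± 0.14). Their adjusted p ran from 4.74e-09 to 0.00382. The named lower genes were Sidpn (-1.50 ± 0.13), Delta (-1.45 ± 0.18), Glut4EF (-1.14 ± 0.16), ken (-1.11 ± 0.11) and Smox (-1.07 ± 0.08), the latter encoding a Smad of activin signalling. With them were Mef2 (-1.0 ± 0.12), a transcription factor gene of muscle and neurons, and emc (-0.95 ± 0.11), which encodes an inhibitor of bHLH factors. The adjusted p of these lower genes ran from 2.58e-08 to 7.74e-05. The sex differentiation gene dsx, chosen after its values were seen, had 3.38 ± 0.222 FPKM in DMSO, 2.47 ± 0.613 in 20E and 5.09 ± 0.459 in JH3. The direct difference was log2 -0.93 ± 0.10 (adjusted p = 4.66e-06, -1.03 and -0.85 within the runs).

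Of the ecdysone list 8 of 18 were higher in 20E and Hr38, which neuronal activity also induces, was lower (log2 -0.81 ± 0.21, adjusted p = 0.0211). There were 9 higher and 2 lower when adjusted over the list alone. Camera gave an adjusted p of 1.64e-05, and adjusted p = 0.308 with an estimated correlation. In the juvenile hormone list Kr-h1 and hry were lower of 3, and jhamt (-2.20 ± 0.68, adjusted p = 0.0741) was lower only when adjusted over the list alone, which gave 3 lower. Camera gave it an adjusted p of 5.22e-05, and adjusted p = 0.0502 with an estimated correlation. By fry both had an adjusted p of 5.37e-05. Within the ecdysone list the higher genes included Eip74EF (1.36 ± 0.10), Cyp18a1 (1.21 ± 0.25), E23 (1.19 ± 0.28), Hr39 (0.56 ± 0.11), Hr3 (0.52 ± 0.10) and Eip63E (0.27 ± 0.07). Not past the threshold were Ecr (-0.09 ± 0.10, adjusted p = 0.679), usp (-0.04 ± 0.16, 0.912) and br (-0.33 ± 0.20, 0.488), nor was Crz (-0.22 ± 0.19, 0.621). The calls of Eip63E (0.24 to 0.25) ended without JH3 replicate 4 or 6. Scaling to total reads (0.21, adjusted p = 0.0526) and removal of the length trend (0.22, adjusted p = 0.0568) ended it too. Those of Hr38 (-0.78 to -0.73) ended without 20E replicate 2 or JH3 replicate 4 or 6, and that of E23 without 20E replicate 6 and JH3 replicate 1 together (1.04).

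In the circadian list 2 of 8 were higher and 2 lower in 20E, also when adjusted over the list alone (camera adjusted p = 0.851, fry for a change in either direction adjusted p = 2.96e-05). Other lists passed this form of fry too, among them the insulin and TOR list (adjusted p = 1.78e-08) and the eye list (adjusted p = 1.44e-06). It was not particular to this comparison. In 20E with DMSO the ecdysone (adjusted p = 1.2e-13), circadian (0.0267), detoxification (7.81e-05) and eye (0.0111) lists passed it. In JH3 with DMSO the ecdysone (adjusted p = 0.00144), circadian (0.0055) and insulin and TOR (0.00401) lists did. In the insulin and TOR list ILP-2 and rictor (0.42 ± 0.09, adjusted p = 0.00914) were higher and foxo lower of 18. There were 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0656). Among the 26 neuropeptide and receptor genes ILP-2 and SIFR (1.09 ± 0.28, adjusted p = 0.0231) were higher, and 5 when adjusted over the list alone (camera adjusted p = 0.00368, adjusted p = 0.424 with an estimated correlation). The SIFR call ended without 20E replicate 3 or JH3 replicate 4 or 6 (0.97 to 1.03). Of 35 receptor genes 5-HT2A (1.30 ± 0.14, adjusted p = 3.75e-06) and nAChRalpha2 (0.35 ± 0.08, adjusted p = 0.014) were higher. There were 3 when adjusted over the list alone (camera adjusted p = 0.0252, adjusted p = 0.699 with an estimated correlation). Without 20E replicate 6 and JH3 replicate 1, nAChRalpha2 (0.27) no longer passed.

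The activity-regulated genes Hr38 and Jra, the fly Jun (-0.57 ± 0.14, adjusted p = 0.0215), were lower of 6. This was also so when adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.308 with an estimated correlation, fry adjusted p = 0.0152). The Jra call ended without any of 20E replicates 3 and 5 or JH3 replicates 1 and 2 (-0.54 to -0.49). Of 18 lipid genes the fatty acid synthase gene FASN1 (0.60 ± 0.14, adjusted p = 0.0149), Mtp (0.56 ± 0.16) and fabp (0.43 ± 0.12) were higher. The lipid droplet gene Lsd-1 (-0.82 ± 0.20, adjusted p = 0.0149) was lower. There were 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0291, adjusted p = 0.598 with an estimated correlation). Lsd-1 did not pass without 20E replicate 6 and JH3 replicate 1 (-0.77). The calls of Mtp (0.48 to 0.58) and fabp (0.36 to 0.45) each ended on leaving out any 1 of 9 libraries. For both these include 20E replicates 1, 2, 3 and 6 and JH3 replicates 2, 3, 5 and 7, with JH3 replicate 1 for Mtp and 20E replicate 7 for fabp. In the detoxification list (14 measured) Cyp18a1 was higher and Cyp4aa1 (-0.59 ± 0.16, adjusted p = 0.0303) lower. There were 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0992). The Cyp4aa1 call ended without any of 20E replicates 1 to 3 or JH3 replicates 1 to 4 and 7 (-0.60 to -0.49).

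Of 9 glial markers 3 were higher in 20E than in JH3, namely moody (0.68 ± 0.12, adjusted p = 0.00103), the engulfment receptor gene drpr (0.55 ± 0.11, adjusted p = 0.00438) and Gli (0.45 ± 0.12, adjusted p = 0.0364). The count was the same when adjusted over the list alone (camera adjusted p = 0.00205, adjusted p = 0.424 with an estimated correlation, fry adjusted p = 0.0414). The Gli call ended without any of 20E replicates 1 to 5 or JH3 replicates 4 and 5 (0.43 to 0.47). Of 16 neuron markers the acetylcholine transporter gene VAChT (0.54 ± 0.11, adjusted p = 0.0045) was higher, also when adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.626 with an estimated correlation). In the eye list rdgA (1.40 ± 0.11, adjusted p = 9.34e-08) and in the cuticle list Gasp were the only calls, also when adjusted over the list alone (camera adjusted p = 0.0902 and 0.239). The gene drpr was the only call among 4 haemocyte markers, also when adjusted over the list alone (0.0637). Ribosomal protein genes (median log2 -0.13) and oxidative phosphorylation genes (median -0.08) had camera adjusted p of 7.55e-05 and 0.0245 without any call, over all genes or adjusted over the list alone. These were adjusted p = 0.653 and adjusted p = 0.699 with an estimated correlation. Over all 9381 genes the log2 fold changes correlated with relative gene length at Spearman 0.32, a trend that can also shift whole lists. Of all camera calls in the 3 comparisons, only the ecdysone list under 20E and the juvenile hormone list under JH3 held with an estimated correlation in the original fit. The immune, heat shock, fat body, muscle, chemosensory, proteasome, ecdysteroid synthesis and head gland lists had no call, over all genes or adjusted over the list alone. Camera, where run, gave adjusted p from 0.116 to 0.885.

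**Figure D3:**
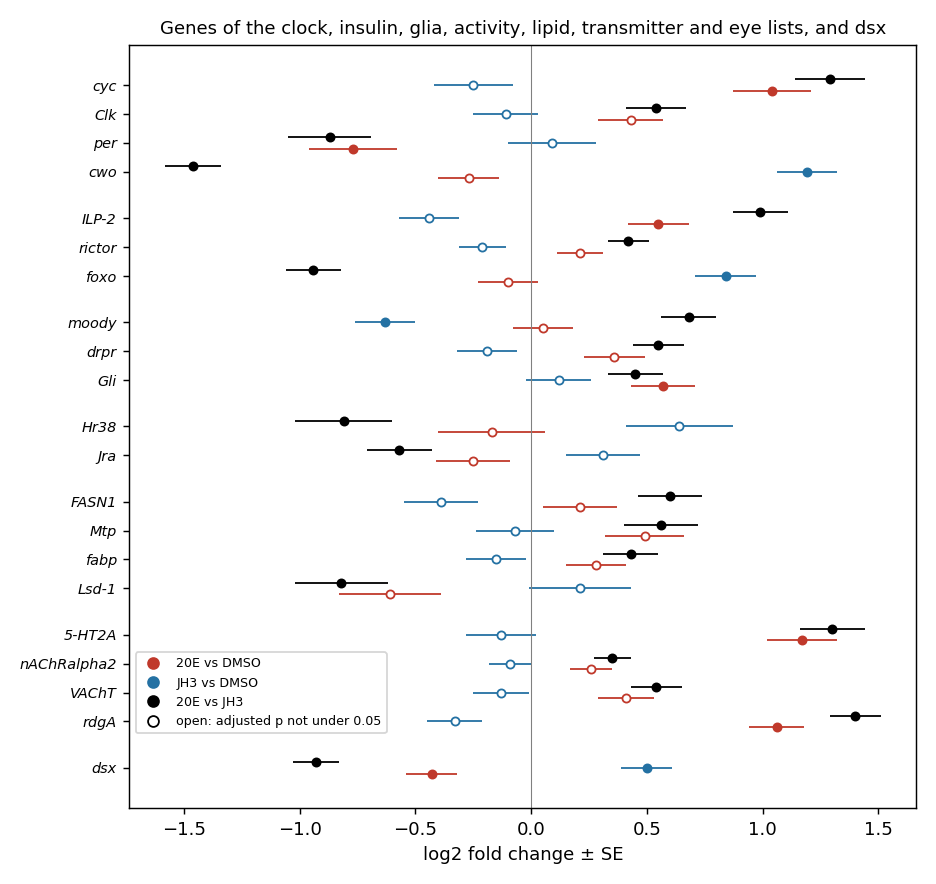
Log2 fold changes ± SE of members of the circadian, insulin, glial, activity, lipid, transmitter and eye lists that passed in 20E with JH3, and of dsx, for 20E with DMSO (red), JH3 with DMSO (blue) and 20E with JH3 (black); open points did not pass. For cyc, ILP-2, foxo, cwo and dsx the direct difference was 1.29, 0.99, -0.94, -1.46 and -0.93.

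The effects of the hormones were also compared across genes. E75 rose under both hormones, as did Traf4 (log2 1.53 ± 0.15 under 20E and 0.86 ± 0.15 under JH3), an adaptor gene of TNF receptor signalling. So did the growth regulator gene Myc (1.0 ± 0.15 and 0.84 ± 0.15), tna (1.02 ± 0.15 and 0.86 ± 0.15) and Pdk1 (0.89 ± 0.17 and 1.26 ± 0.17). Toll-6 (-0.81 and -0.75), Gycalpha99B (-1.0 and -0.71) and nab (-0.42 and -0.44) fell under both. Opposite calls were few. The genes klu (-0.67 and 1.27), dsx (-0.43 ± 0.11 and 0.50 ± 0.11) and LOC105192284 (-0.65 ± 0.11 and 0.59 ± 0.11) fell under 20E and rose under JH3. The gene spri (0.93 ± 0.15 and -0.66 ± 0.15) did the reverse. Traf4, Myc, tna, nab, dsx and LOC105192284 are named because of these values, and likewise Pdk1 and spri under 20E. The calls of dsx against DMSO ended without any of DMSO replicates 1 to 4 or 20E replicates 2, 3, 5 and 7 under 20E (-0.44 to -0.37). Under JH3 they ended without any of DMSO replicates 1, 3, 4 and 5 or JH3 replicates 1 to 3 and 5 to 7 (0.45 to 0.52). Quantile normalization ended both dsx calls (-0.45, adjusted p = 0.0849, and 0.46, adjusted p = 0.128). The call under JH3 also ended with the length trend removed (0.46, adjusted p = 0.164), total reads (0.50, adjusted p = 0.052) and no filter (0.50, adjusted p = 0.0602), so its opposite calls against DMSO are less certain than the direct difference. That of spri under JH3 ended without any of DMSO replicates 2 to 5 or JH3 replicates 1 and 4 to 7 (-0.70 to -0.55).

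Over both comparisons 19 genes were called higher in both, 10 lower in both and 4 in opposite directions. Independent lists of these sizes would share 1.53, 0.21 and 1.17, values that take no account of the shared DMSO libraries, which by themselves favour estimates in the same direction. Of the 29 genes called in the same direction, 22 did not pass in the direct comparison. Across the 9381 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.27 (Spearman 0.32, and Pearson 0.34 and 0.40 within the runs). Without 20E replicate 6 and JH3 replicate 1 it was Pearson r = 0.41. Unchanged groups against shared DMSO libraries gave a mean r of 0.58 (0.04 to 0.90), and with the DMSO libraries split into disjoint sets the median r was -0.08 (-0.31 to 0.08 over 20 splits). The covariance was 0.0153 against 0.0266 ± 0.0153 in the simulations, a difference of -0.0113, so a shared effect across all genes was not detectable.

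**Figure D4:**
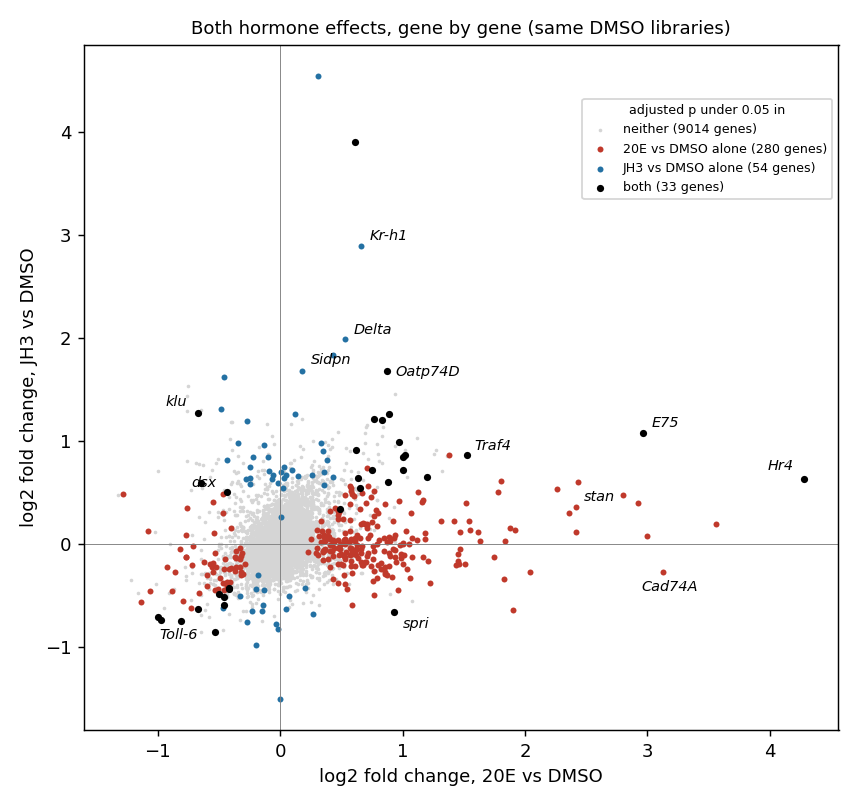
Log2 fold change of each of the 9381 tested genes under JH3 against that under 20E, both relative to the same 5 DMSO libraries, coloured by the comparisons in which the adjusted p was under 0.05. Hr4, E75 and Cad74A lie far to the right (4.28, 2.96 and 3.13), Kr-h1 and Delta high on the JH3 axis (2.90 and 1.99), and klu, dsx and spri among the 4 genes called in opposite directions.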

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

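Of 261 groups of libraries examined (86 named genes and the read depth, 3 groups each), 15 (5.7%) held a library far from the others of its group for its range, and chance alone gives about 1 in 20. The tests on Kr-h1 in 20E replicate 6, the test of 20E replicate 6 alone and the test of glial cell number were chosen after the results they measure had been seen.

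In 20E replicate 6, Kr-h1 stood at 14.4 FPKM against 1.72 to 2.91 in the other 20E libraries, and Delta at 21.6 against 8.33 to 10.6, both toward the JH3 group. RNA or a label from a JH3 sample would have raised the genes that respond most to JH3 in step, since Kr-h1 lay 75.8% of the way to the JH3 mean. LOC105186969 was at 6.76 FPKM against at least 66.6 in JH3, only 3.15% of the way, and LOC105192299 at 0.661 against at least 8.28, which argues against such a mix. The library also deviated as a whole (array weight 0.14, residual SD 0.544), and a line through the other 18 libraries put Kr-h1 1.09 prediction SDs above what that deviation would give. As no other library deviated as far (a score of 0.97 against at most 0.27), the whole-library deviation and a real response in this ant cannot be told apart, and no biological explanation was tested.

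The same library was high for Clk (21.7 FPKM against 12.1 to 14.1), sev (20.7 against 10.6 to 14.1) and VAChT (74.3 against 42.9 to 54). JH3 replicate 1 was low for drpr (10.1 against 17.2 to 23.3) and per (5.56 against 10 to 14.1) and high for ken (25.6 against 14.9 to 18.3). JH3 replicate 3 was low for Delta (16 FPKM against 27.8 to 38.7), Ets98B (1.75 against 2.15 to 2.41) and chinmo (9.79 against 14.5 to 16.8). DMSO replicate 2 was high for Gasp (1.52 FPKM against 0.154 to 0.357), and DMSO replicate 5 low for sing (0.0972 against 0.237 to 0.264) and LOC105192284 (7.74 against 9.75 to 10.2). JH3 replicate 5 was high for LOC105187714 (1.78 against 0.612 to 0.934).

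The rise under 20E of the 7 genes outside the ecdysone list among the 10 largest named rises (Cad74A, sing, stan, Np, Gasp, oys and pyd, median log2 2.04) could come from other tissue carried over in the 20E dissections, from 20E replicate 6 alone, or from a gene length trend between libraries. Carried-over tissue would raise the markers of cuticle, muscle, fat body, haemocytes and head glands, yet 0% of the other 47 passed upwards, with a median log2 of 0.00 ± 0.29 (SD) and a highest value of 0.51. Gasp, a member of the cuticle list that rose, is among the 7 genes and was not counted. For genes chosen as the largest rises in these same libraries, the next checks are not independent support. All 7 genes passed without 20E replicate 6, and with the length trend removed their median was 2.01. These values argue against each of the 3, for the tissues that the lists cover; tracheae and other tissues without a list stay open. A response of brain cells to 20E is a hypothesis that these libraries, which hold whole central brains, leave untested.

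The lower estimates of glial markers under JH3 (8 of 9 below DMSO, 2 of them past the threshold, median log2 -0.30) may reflect fewer glial cells in the JH3 dissections or the gene length trend. Under 20E the median of the 9 was -0.13, with 2 higher and 2 lower when adjusted over the list alone. Gat-a stood at 27.8 to 44.8 FPKM in 20E against 48 to 63.5 in DMSO. The fall was thus not particular to JH3 for every marker, and the part that the shared DMSO libraries play in it was not tested. Fewer glia would lower the 9 markers alike only if no other cells expressed them, and drpr is also on the haemocyte list. The changes ran from -0.63 ± 0.13 (moody) to 0.12 ± 0.14 (Gli). Exchanging JH3 and DMSO labels within the runs gave as much heterogeneity in 3 of 300 arrangements (exact permutation p = 0.01). This argues against an equal fall of the 9 markers but cannot decide on the number of glia. A chi-square test that took the markers as independent, run before it, had given 0.000562 and is not relied on. With the length trend removed the median stayed at -0.28 and 2 markers passed. Fewer glial cells stay open, and a loss of some glial types, or lower expression per cell under JH3, stays open as an untested hypothesis.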

How the results depend on the processing

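No gene called in the 3 comparisons changed sign under any alternative run. The tests with voom, total reads, the gene length trend and both doubted libraries left out were added after the data were seen. Before removal of that trend, log2 fold changes correlated with relative gene length in each comparison. Spearman values were 0.13 for 20E with DMSO, -0.21 for JH3 with DMSO and 0.32 for 20E with JH3. Without the run term the calls were 193 for 20E with DMSO, 49 for JH3 with DMSO and 313 for 20E with JH3. In run 190514 alone they were 120, 14 and 169 and in run 200212 alone 50, 8 and 160, from fewer samples. With library weights they were 551, 180 and 788. For JH3 with DMSO scaling to total reads gave 151, removing the gene length trend 159, and leaving out 20E replicate 6 and JH3 replicate 1 134; elsewhere the cause of these shifts was not tested. Leaving out each library in turn gave 219 to 354, 60 to 88 and 414 to 569 calls. Voom on the reads read back gave 308, 93 and 500, of which 297, 85 and 485 were among the original calls.

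Lists past camera (2 for 20E with DMSO, 5 for JH3 with DMSO, 10 for 20E with JH3) numbered 1, 1 and 0 with an estimated correlation. By fry for a shared direction of change, 1, 1 and 6 lists passed, of which the haemocyte markers in 20E with JH3 had not passed camera. At the preset correlation, 1 list passed for 20E with DMSO and 5 for 20E with JH3 with the length trend removed, and 1 for 20E with DMSO and 3 for JH3 with DMSO without both doubted libraries. With an estimated correlation the ecdysone list for 20E with DMSO was lost without both doubted libraries (adjusted p = 0.238). The correlation of the hormone effects was -0.08 with the DMSO libraries split.

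The replicate number as a block gave 274, 96 and 531 calls, and with it the juvenile hormone list for JH3 with DMSO was lost with an estimated correlation (adjusted p = 0.0612). Whether the numbers pair the ants is not settled. Libraries with the same number correlated at -0.43 to 0.37 after group and run means were removed. Their median was 0.02, against -0.05 for other pairs of the same run. Of 17 pairs 5 were over 0.1. Among libraries of the other groups in the same run, 9 of 19 libraries correlated best with their own number. How many would do so by chance was not determined.

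Values that changed sign belonged to genes without a call. For 20E with DMSO, Hr38 was 0.01 without the run term. Ecr was -0.02 in run 190514, -0.02 with total reads, -0.11 with the length trend removed and -0.01 without both doubted libraries. There br was -0.20 in run 200212, -0.06 without both doubted libraries and -0.12 to 0.21 with 1 library left out. For JH3 with DMSO, br was -0.03 and Hr3 -0.05 in run 200212. Crz was -0.03 without the run term, -0.18 in run 190514, -0.07 with library weights, -0.02 by voom, -0.08 with the length trend removed, -0.01 without both doubted libraries and -0.06 to 0.15 with 1 library left out. For 20E with JH3, Ecr was 0.07 and usp 0.18 in run 200212, and usp -0.14 to 0.06 with 1 library left out.

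For JH3 with DMSO, usp, without a call, passed in run 190514 (0.87) and with the length trend removed (0.51). Besides the run term, single runs and single libraries, another alternative also ended some calls. Among them were those of per, sev, SIFR, Gli, dsx, Dscam2, bark and gro (20E with DMSO), spri, Gat-a, Gprk1, Hr4 and dsx (JH3 with DMSO), and Eip63E, E23, Hr38, SIFR, nAChRalpha2, Cyp4aa1, Lsd-1, fabp, Mtp and Gli (20E with JH3). Among the named genes with a call, 14 of 52 (20E with DMSO), 3 of 33 (JH3 with DMSO) and 28 of 58 (20E with JH3) kept it under every alternative in which they were tested. At the filter of 5 FPKM 37 of the 52, 25 of the 33 and 48 of the 58 were tested.

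Among 100 splits of the libraries into groups of the real sizes, the real one included, only the real one reached its count in each comparison (1 of 100), so a chance division of the libraries does not account for the counts. The highest other split gave 248 genes for 20E with DMSO against 313, 2 for JH3 with DMSO against 87 and 39 for 20E with JH3 against 501. The split with 248 genes set 5 of the 20E libraries against the 5 DMSO libraries with 20E replicates 4 and 7, and so kept much of the real contrast.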

Other observations

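In a list of 46 measured genes of cell adhesion, junctions and planar polarity, 10 were higher in 20E than in DMSO and none lower (camera p = 0.0817 with an estimated correlation). They included sdk (log2 1.13 ± 0.19), a junction adhesion gene, vari (0.77 ± 0.12), a septate junction scaffold gene, Dscam2 (0.99 ± 0.24), a gene of neuronal self-avoidance, and bark (0.98 ± 0.22), a gene of tricellular junctions. Against JH3, 16 were higher in 20E and 1 lower. None passed in JH3 with DMSO. The Dscam2 call ended without DMSO replicate 1 or 3 or 20E replicate 1 or 3 (0.77 to 0.96), and that of bark without DMSO replicate 4 or 5 (0.93 to 0.94).

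In a list of 27 measured Notch pathway genes and bHLH repressors, 6 rose under JH3 and none fell (camera p = 0.144 with an estimated correlation). They were Delta, Sidpn, klu, cwo, hry and neur (0.57 ± 0.12), which encodes the ubiquitin ligase that activates Delta. The neur call ended without any of DMSO replicates 1, 3 and 4 or JH3 replicate 2 (0.51 to 0.57). Under 20E kuz (0.80 ± 0.12), whose protease cleaves Notch, and gro rose, and 3 genes fell. The call of gro (0.42 to 0.50) ended without any of DMSO replicates 1 to 4 or 20E replicates 1 to 3.

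Both lists and their tests were chosen after the values were seen. That JH3 acts on Notch genes as a group is a hypothesis for which camera gave p = 6.12e-04 and, with an estimated correlation, p = 0.144; the median log2 fold change of the list was -0.02 and the mean 0.24. That 20E acts on adhesion and junction genes as a group is a hypothesis for which camera gave p = 7.64e-11 and, with an estimated correlation, p = 0.0817, with a median of 0.13 and a mean of 0.36. Neither is settled by these tests, since a few strong members may carry the preset test and the lists include genes that prompted them.

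The gene jhamt, whose enzyme makes juvenile hormone in the corpora allata, gland bodies next to the brain, was either near zero or clearly present. It was 1.95 to 8.44 FPKM in 13 libraries and 0.0138 to 0.055 in 6. It was present in 7 of 7 JH3, 3 of 7 20E and 3 of 5 DMSO libraries, and did not pass over all genes in any comparison. It is one of the 3 measured members behind the call of the juvenile hormone list, and was lower in 20E than in JH3 when adjusted over that list alone. The 20E libraries with it were replicates 3 (1.95 FPKM), 4 (3.4) and 6 (5.58), and the DMSO libraries replicates 1 (4.77), 3 (4.55) and 5 (4.1).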
